A study of Homo sapiens with 4 samples.

How the data were processed

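Total RNA from OCI-AML2 cells was isolated on RNeasy columns, and stranded libraries were made after ribosomal RNA depletion, per the labels' protocols. The 4 samples form 2 groups of 2, control (scrambled hairpin) and SOCS1 overexpression (open reading frame), so the vector type differs between the groups together with SOCS1. The submitters' processing notes name Salmon 1.4.0, STAR, DESeq2 and the GRCh38 build, without roles or order; versions of STAR and DESeq2 and the annotation release are not given in the sources used here.

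The deposited values are estimated counts per gene (expected counts) in whole numbers, with Ensembl identifiers and symbols. The name of the table calls them normalised, but totals, upper quartiles (207, 213, 181 and 179 counts) and median-of-ratios factors (1.07, 1.08, 0.938 and 0.925, for control lanes 1 and 6 and overexpression lanes 1 and 6) differed between libraries, so they were treated as counts not scaled for library size, and the other reading was tried as an alternative. The column names give the group and a lane number but no replicate number, so columns were assigned to groups and not to single samples. There were 0 columns of other samples.

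Values were rounded to whole numbers. Genes were kept with filterByExpr (12342 of 34489), scaled with TMM and tested with edgeR 4.0.16 (quasi-likelihood test, two-sided, prior count 0.125) in R 4.3.3, with Benjamini-Hochberg adjusted p under 0.05 as the threshold and no covariate. All adjusted p-values of genes are from this test unless another is named. CPM values are counts divided by the TMM-scaled library size, in edgeR's usual unit. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation, and with fry, for the 31 of 34 lists with at least 5 tested members, adjusted over the lists. With estimated correlations 0 lists were called. That version rests on the few degrees of freedom that 4 libraries leave, so a call lost there need not mean that the genes are correlated. Fry, which asks whether a list's genes move one way and does not compare them with other genes, called 12. Intervals are 95%; counting intervals and floors (3 counts) cover counting error only. Positions, transcript GC and length, and the share of 31-base words found in other genes came from GENCODE release 29 on GRCh38, matched by identifier without version for 12316 of the tested genes; SAGSIN1 was not matched.

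A main test for each kind of value was fixed before the data were examined. The edgeR test, the one for counts, was used once the values had been read as counts. The gene lists and the rule for named genes were also fixed beforehand. The rule took SOCS1; then, among genes past the threshold with non-overlapping groups and either a mean in the upper part of tested genes (at or above the median) or at least 50 normalised counts, whichever admitted more, the 12 largest rises and the 12 largest falls; and from each list up to 4 members with the smallest p, with the 2 most abundant members for lists of other cell types. Genes named outside it are said to have been chosen after their values were seen. The value of 1 further gene is not reported here. The alternatives chosen in advance were other scale factors, quantile normalization, other prior counts (0.5 and 5), no filter on low counts, a mean count of at least 50, limma with and without a trend, DESeq2 1.42.0, a size threshold, leaving out each library, and leaving out RNA-class lists or SOCS1. A lane term, values taken as already normalised, and removal of each library's trend on GC content and length were added after seeing the data.

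Within groups, counts differed beyond sampling noise (chi-square per gene 3.04 in control and 2.77 under overexpression), so all 4 libraries were kept as separate. The common biological coefficient of variation was 0.041. Simulated data were drawn from these libraries' means, sizes and dispersions, with 200 of 12342 genes changed. There the edgeR test recovered 30% of genes changed 1.2-fold, 68% at 1.5-fold, 78% at 2-fold and 94% at 4-fold, and 10.6% of its calls were false. Far more genes were called in the real data (3512). Recovery and the false share both depend on how many genes change, so these figures need not hold for the real calls.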

Results

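RNA was profiled in OCI-AML2, a human cell line established from acute myeloid leukaemia. Control cells carried a scrambled short hairpin RNA, and the other cells carried an open reading frame for SOCS1, a feedback inhibitor of JAK-STAT cytokine signalling. Each group had 2 libraries, and each of the 2 sequencing lanes named in the table (lanes 1 and 6) held 1 library of each group. Summed estimated counts were 16551985 and 16775282 in the control libraries of lanes 1 and 6. They were 14577056 and 14389786 in the overexpression libraries of lanes 1 and 6. Of 34489 genes, 17671 were at 0 in all 4 libraries and 12342 had enough counts to be tested. Log2 expression correlated across genes at r = 0.987 within each group and between 0.974 and 0.976 across groups. The first principal component held 59.0% of the variance and separated the groups.

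The first comparison asked whether the SOCS1 transcript was higher where the labels say it was overexpressed. SOCS1 (ENSG00000185338; GRCh38, chromosome 16, 11254405 to 11256200, minus strand) was a low transcript in every library. The control libraries held 33 and 12 counts in lanes 1 and 6, and the overexpression libraries held 45 and 33. Mean expression was 1.35 ± 0.90 CPM (counts scaled to library size; SD, n = 2) in control and 2.70 ± 0.562 CPM (SD, n = 2) under overexpression. The log2 fold change of 1.00 (SE 0.45) did not pass the threshold in the edgeR quasi-likelihood test (adjusted p = 0.135), and the 95% interval of the fold ran from 0.979 to 4.10. Within lanes the log2 difference was 0.61 in lane 1 and 1.53 in lane 6. Without the control library of lane 1 it was 1.91 (adjusted p = 0.0291), and without the control library of lane 6 it was 0.44 (adjusted p = 0.487). With lane as a term of the model it was 1.08 (adjusted p = 0.0399). Because the transcript level does not settle the labels, directions below refer to the libraries labelled SOCS1 overexpression.

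The second comparison asked which transcripts differed between the libraries labelled SOCS1 overexpression and the control libraries. IGSF10, an immunoglobulin-superfamily gene (ENSG00000152580; chromosome 3, 151425384 to 151458709), rose from 61.3 ± 3.52 to 224 ± 7.59 CPM (SD, n = 2 each; log2 fold change 1.87, SE 0.053, adjusted p = 4.8e-07). PRSS57, a serine protease of neutrophil granules (ENSG00000185198; chromosome 19, 685546 to 695498), rose from 2.09 ± 0.018 to 19.9 ± 0.535 CPM (log2 fold change 3.24, SE 0.14, adjusted p = 3.32e-06). MEGF6 (ENSG00000162591; chromosome 1, 3489920 to 3611495) fell from 38.6 ± 1.33 to 0.312 ± 0.052 CPM (log2 fold change -6.92, SE 0.17, adjusted p = 1.95e-07). FSCN1, which encodes the actin-bundling protein fascin (ENSG00000075618; chromosome 7, 5592823 to 5606655), fell from 32.1 ± 0.861 to 4.06 ± 0.775 CPM (log2 fold change -2.98, SE 0.13, adjusted p = 2.89e-06). In all, 3512 of 12342 genes passed, 1739 higher and 1773 lower, and 361 of them changed by 2-fold or more (145 higher, 216 lower). The count depended on the tool: DESeq2 called 1987 genes and limma without the trend 1154.

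Several of the largest changes were close to on or off. Such switches (at most 3 counts in both libraries of one side, at least 30 in both of the other) numbered 3 in each direction between groups. The split by lane held 4, so some switches occurred without a difference in group. SAGSIN1 was at 0 in both control libraries and at 309 and 273 counts in the overexpression libraries of lanes 1 and 6, at least 105.5-fold higher against a floor of 3 counts per library. CPEB2, a regulator of mRNA translation, had 1 and 0 counts in control and 180 and 34 under overexpression in lanes 1 and 6, a ratio of 248 (95% counting interval 44.0 to 9836). Against the floor of 3 counts per library it was at least 13.1-fold higher. Its log2 fold change of 7.61 was 6.755 without the control library of lane 6, 5.98 without the overexpression library of lane 1 and 8.36 without that of lane 6; without the control library of lane 1 no fold could be measured, since the other had 0 counts. FAM220A went the other way, with 390 and 389 counts in control against 2 and 1 in lanes 1 and 6, a ratio of 0.00446 (95% counting interval 0.000918 to 0.0131).

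The other large rises, as log2 fold changes, were in MPP7 (2.24), FBXO15 (2.18), SKA1 (2.16), ZBTB22 (2.13), RNASE3 (2.13), HIVEP2 (1.99), ARAP2 (1.92) and FAM163A (1.84). RNASE3 encodes the eosinophil cationic protein, and SKA1 a protein of the spindle and kinetochore. ZBTB22 lost its call without either control library (adjusted p = 0.0625 and 0.0766) and without the overexpression library of lane 1 (log2 fold change 0.63, adjusted p = 0.287), while without that of lane 6 its value was 2.85. SKA1 was at 1.55 without the control library of lane 1 and 3.25 without that of lane 6, and lost its call with DESeq2 (adjusted p = 0.0506), limma without the trend (0.110) and limma-trend with robust estimation (0.202). ZBTB22 also lost its call with each of these 3 tools, with quantile normalization and with no filter on low counts (adjusted p between 0.0736 and 0.349). HIVEP2 was at 2.64 without the control library of lane 1. The other large falls were in FCGR2B (-4.62), FCGR2C (-3.86), HSPA7 (-3.57), SULF2 (-2.93), MOAP1 (-2.85), MMP9 (-2.80), TBL1X (-2.75), ENO2 (-2.45) and OSCAR (-2.28). FCGR2B and FCGR2C are Fc gamma receptor genes, MMP9 encodes a secreted matrix protease and ENO2 a glycolytic enolase. FCGR2C (from 161581339), HSPA7 (from 161606291) and FCGR2B (from 161663147) lie close together on chromosome 1, so their falls may not be independent. The annotation lists FCGR2C as a polymorphic pseudogene and HSPA7 as an unprocessed pseudogene. MOAP1 was at -2.10 without the control library of lane 1. With limma without the trend, CPEB2, HIVEP2 and MOAP1 did not pass (adjusted p = 0.0571, 0.0656 and 0.0587). Counts of near-identical genes are uncertain: 52.3% of the 31-base words of FCGR2C, 14.3% of FCGR2B, 69.9% of HSPA7 and 15.5% of RNASE3 also occur in transcripts of another gene.

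**Figure D1:**
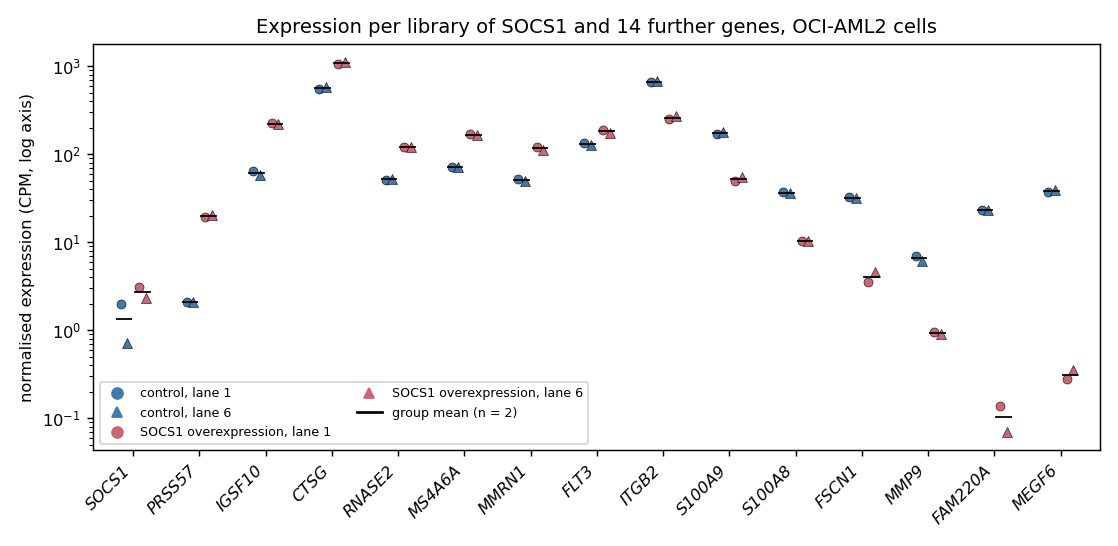
Normalised expression (CPM, log axis) of SOCS1 and 14 further genes in each of the 4 libraries, with blue for control, red for SOCS1 overexpression, circles for lane 1, triangles for lane 6 and bars for group means (n = 2). SOCS1 means were 1.35 and 2.70 CPM with a wide spread between libraries, while ITGB2 lay at 668 CPM in control and 261 CPM under overexpression.

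Each of the 3512 genes had groups that did not overlap, which with 1 library of each group per lane forces the same sign in both lanes. Genes that pass the test are nearly bound to have such groups, so this is no separate support for the calls. Among all tested genes 65.4% had groups that did not overlap, against 33.3% by chance. Nothing in the labels says that the libraries came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Taking the deposited values as already normalised, with no scaling for library size, gave 530 higher and 5435 lower genes, with the median log2 fold change of all genes at -0.21. Without the control library of lane 1 the count was 2311.

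**Figure D2:**
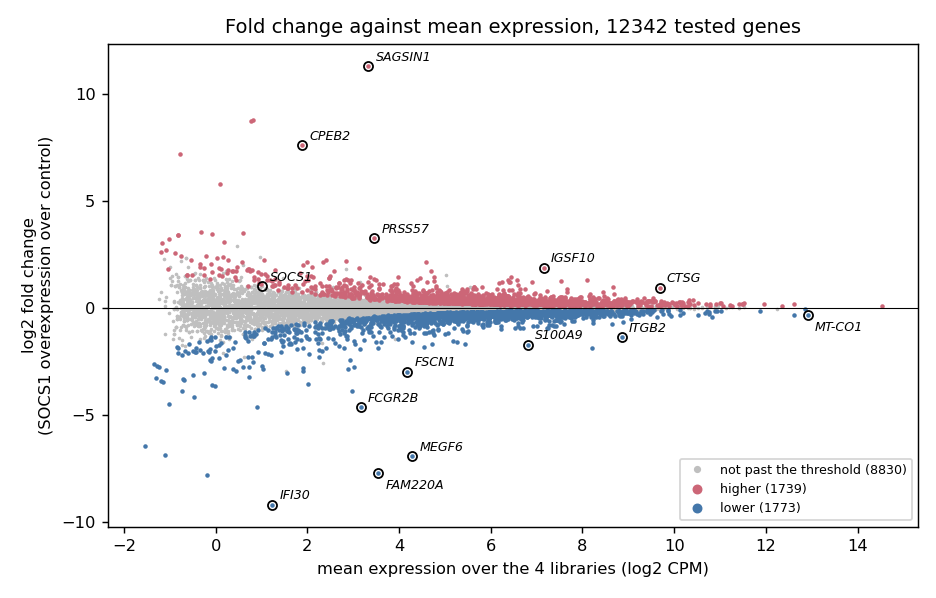
Log2 fold change (SOCS1 overexpression over control) against mean expression (log2 CPM) for the 12342 tested genes, with 1739 higher genes in red, 1773 lower genes in blue and the rest in grey. Circled genes are named, and the plotted values of SAGSIN1 and IFI30, which had 0 counts in a group, depend on the prior count and are not measured folds.

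Myeloid genes moved in opposite directions. Among 32 measured monocyte and macrophage genes, 3 rose, 17 fell and 12 did not pass (3 and 18 adjusted over the list alone). The calprotectin genes S100A9 and S100A8 fell by 1.72 and 1.83 on the log2 scale, from 173 to 52.4 CPM and from 36.4 to 10.3 CPM. The Fc receptor gene FCGR2A fell by 0.78, with 24.0% of its words shared with other genes, and MS4A6A rose by 1.23. The list was lower by camera with a preset correlation (median log2 fold change -0.34, adjusted p = 1.52e-08; adjusted p = 0.250 with an estimated correlation). Of 15 granulocyte genes, 8 rose, 4 fell and 3 did not pass, with the same counts adjusted over the list alone. CTSG, the azurophil granule protease cathepsin G, rose from 566 ± 22.1 to 1080 ± 36.8 CPM (SD, n = 2 each; log2 fold change 0.93, SE 0.037, adjusted p = 1.94e-06). RNASE2, which encodes an eosinophil ribonuclease, rose from 52.1 to 120 CPM, and BPI, which encodes an antibacterial granule protein, rose from 11.9 to 26.5 CPM. ITGB2, the shared beta chain of the leukocyte integrins, fell from 668 ± 17.9 to 261 ± 12.5 CPM (log2 fold change -1.36, SE 0.041, adjusted p = 5.94e-07). The granulocyte list was called higher (median 0.19, adjusted p = 0.0446; adjusted p = 0.452 with an estimated correlation), but its mean was -0.05, and it was called under 4 of 14 other settings that gave different list p-values, 2 of which left out only SOCS1 or the RNA-class lists and 1 only changed the scale factors. The call was lost without the control library of lane 1 and without either overexpression library, with lane as a term of the model (adjusted p = 0.116), with the GC and length trend removed (0.397), with quantile normalization, with no filter, with a mean count of at least 50, with limma and with the deposited values taken as already normalised (0.177).

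Of 23 adhesion and homing genes, 4 rose, 13 fell and 6 did not pass (5 and 14 adjusted over the list alone). After ITGB2, the smallest p-values belonged to the chemokine receptor gene CCR1 (-0.58) and the integrin genes ITGB7 (-0.66) and ITGA4 (-0.35). The list was lower (median -0.25, adjusted p = 6.06e-06; adjusted p = 0.250 with an estimated correlation). Of 22 haematopoietic cytokine receptor genes, 1 rose, 12 fell and 9 did not pass (1 and 13 adjusted over the list alone; median -0.20, adjusted p = 2.39e-04; adjusted p = 0.452 with an estimated correlation). IL13RA1 (-0.66), IFNGR1 (-0.54) and IL1RAP (-0.37) fell, while FLT3, a receptor tyrosine kinase of early progenitors, rose from 132 ± 4.91 to 182 ± 8.64 CPM (log2 fold change 0.46). Of 21 stem and progenitor genes, 7 rose, 3 fell and 11 did not pass, also adjusted over the list alone. MMRN1 rose from 51.0 to 117 CPM and CDK6 from 494 to 667 CPM, and LMO2 fell from 174 to 121 CPM. This list was higher (median 0.075, adjusted p = 0.0262; adjusted p = 0.452 with an estimated correlation), and the call was lost without the control library of lane 6 (0.0593), with quantile normalization (0.333), with no filter (0.299), with limma (0.320) and with the deposited values taken as already normalised (0.168).

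**Figure D3:**
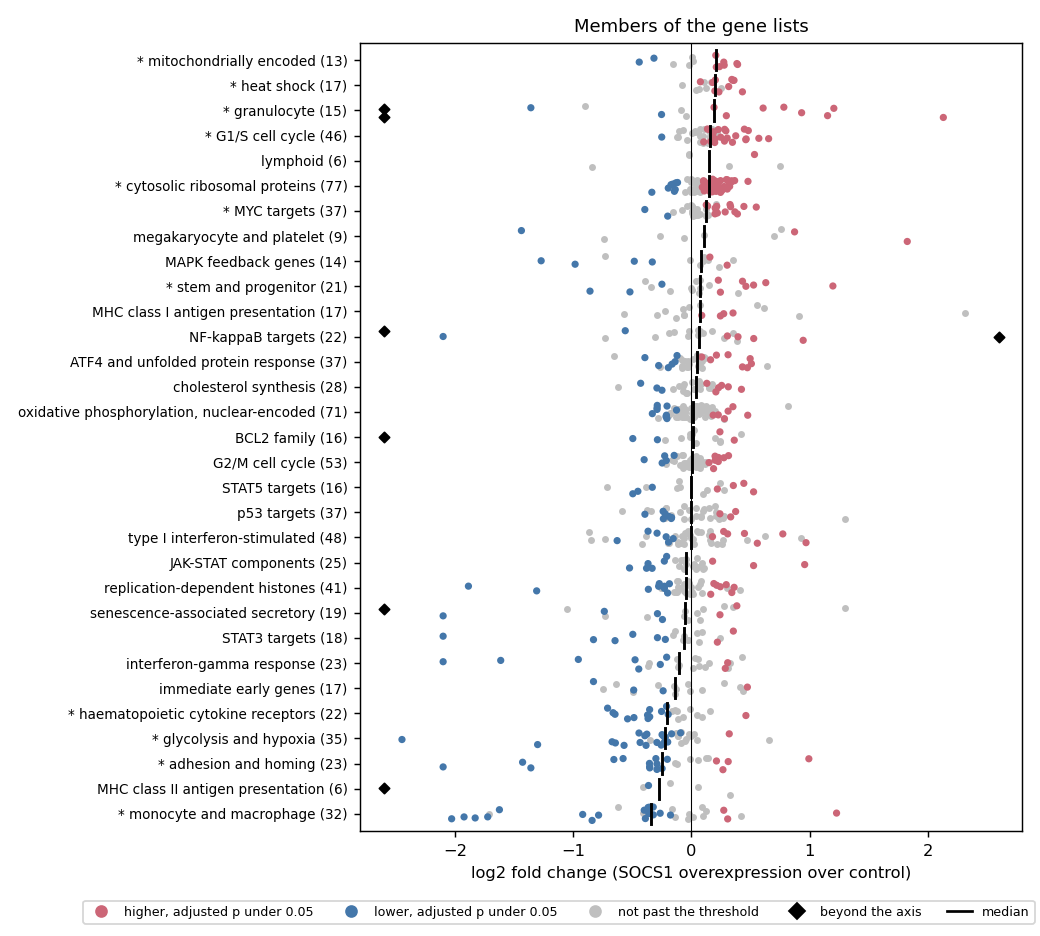
Log2 fold changes (SOCS1 overexpression over control) of the members of the 31 tested gene lists, sorted by their median (black bars), with the number of tested members in parentheses and a star where camera with a preset correlation called the list. Red and blue points are genes past the threshold, grey points are not, and diamonds at the edges are genes beyond the axis; the monocyte and macrophage list has the lowest median (-0.34).

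Of 77 cytosolic ribosomal protein genes, 46 rose, 8 fell and 23 did not pass (49 and 8 adjusted over the list alone), led by RPS27 (0.48), RPS20 (0.30), RPL17 (0.30) and RPL37 (0.33). The list was higher (median 0.15, adjusted p = 2.53e-10; adjusted p = 0.489 with an estimated correlation), but fry did not call it (adjusted p = 0.0503). Of 46 G1/S genes, 22 rose, 1 fell and 23 did not pass (24 and 1 adjusted over the list alone; median 0.16, adjusted p = 4.11e-06; adjusted p = 0.250 with an estimated correlation). UHRF1 (0.65), a factor that maintains DNA methylation, and the replicative helicase genes MCM5 (0.45), MCM6 (0.30) and MCM2 (0.35) had the smallest p-values. Of 37 MYC targets, 14 rose, 2 fell and 21 did not pass, also adjusted over the list alone (median 0.12, adjusted p = 0.0159; adjusted p = 0.452 with an estimated correlation and 0.0503 by fry). SRM (0.55) and ODC1 (0.44), enzymes of polyamine synthesis, rose, and the hexokinase gene HK2 fell by 0.39. Of 17 heat shock genes, 10 rose, 0 fell and 7 did not pass (11 and 0 adjusted over the list alone; median 0.20, adjusted p = 3.9e-05; adjusted p = 0.250 with an estimated correlation), with HSPH1 at 0.43, HSPA8 at 0.23 and STIP1 at 0.36. With the deposited values taken as already normalised, camera did not call the ribosomal protein, MYC and heat shock lists (adjusted p = 0.919, 0.686 and 0.122). Folds then shifted down, with the median of all genes at -0.21. The lowest medians of these lists under any setting in which lists were tested were -0.064, -0.092 and -0.013, so they still lay above that median.

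Of 35 glycolysis and hypoxia genes, 1 rose, 20 fell and 14 did not pass (1 and 23 adjusted over the list alone). DDIT4 and BNIP3, both induced by low oxygen, fell by 0.64 and 0.67 on the log2 scale. PGAM1, a glycolytic mutase, fell from 1110 ± 1.41 to 852 ± 12.7 CPM (log2 fold change -0.38), and the glucose transporter gene SLC2A3 fell by 0.57. Their counts are uncertain, since 34.9% of the words of PGAM1, 29.9% of SLC2A3 and 19.0% of BNIP3 also occur in another gene. The list was lower (median -0.22, adjusted p = 7.28e-13; adjusted p = 0.250 with an estimated correlation). Of 13 mitochondrially encoded genes, 7 rose, 2 fell and 4 did not pass, also adjusted over the list alone (median 0.21, adjusted p = 0.0353; adjusted p = 0.557 with an estimated correlation and 0.0503 by fry). The most abundant named member, MT-CO1, fell from 8561 ± 61.3 to 6876 ± 108 CPM (log2 fold change -0.32), while MT-ND5 (0.39) and MT-ND2 (0.28) rose. Their summed share of counts was 1.81% and 1.82% in the control libraries and 1.69% and 1.68% in the overexpression libraries of lanes 1 and 6. The call was lost without the control library of lane 1 (adjusted p = 0.101), with the GC and length trend removed (0.0906), with the deposited values taken as already normalised (0.876), with quantile normalization (0.523), with no filter (0.0781) and with limma (0.303). Counts of these genes are uncertain, since 66.7% of the 31-base words of MT-CO1, 56.9% of MT-ND2 and 15.1% of MT-ND5 also occur in another gene.

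Camera did not call the lists of interferon response, STAT targets and JAK-STAT components, the pathway that SOCS1 inhibits. It did call the haematopoietic cytokine receptor list lower, as given above (adjusted p = 2.39e-04). By fry, which asks only whether a list's genes move one way, STAT3 targets (adjusted p = 0.0215) and JAK-STAT components (adjusted p = 0.0318) were lower, and with the deposited values taken as already normalised camera also called STAT3 targets lower (adjusted p = 0.0284). Of 48 type I interferon-stimulated genes, 7 rose, 6 fell and 35 did not pass (7 and 5 adjusted over the list alone; median -0.006, mean 0.022, adjusted p = 0.851). DDX60L (-0.63) and STAT2 (-0.37) fell, and PARP14 (0.31) and IFIH1 (0.97) rose. Of 23 interferon-gamma response genes, 2 rose, 7 fell and 14 did not pass, also adjusted over the list alone (median -0.11, adjusted p = 0.140). TYMP (-0.96), APOL1 (-1.61) and TNFSF10 (-0.44) fell, and the myeloid transcription factor gene IRF8 rose by 0.31. Of 16 STAT5 targets, 4 rose, 3 fell and 9 did not pass (5 and 3 adjusted over the list alone; median 0.001, mean -0.025, adjusted p = 0.981). The cell survival gene MCL1 fell from 304 ± 6.01 to 216 ± 5.27 CPM (SD, n = 2 each; log2 fold change -0.50), CD69 fell by 0.45, and CCND3 (0.44) and SOCS2 (0.53) rose. Of 18 STAT3 targets, 2 rose, 6 fell and 10 did not pass (3 and 6 adjusted over the list alone; median -0.066, adjusted p = 0.0871), with FOS at -0.83, IL10RA at -0.65 and MYC at 0.22. Of 25 JAK-STAT components, 3 rose, 6 fell and 16 did not pass (4 and 6 adjusted over the list alone; median -0.042, adjusted p = 0.696). JAK3 rose by 0.96, and STAT6 fell by 0.23. CISH, a further gene of this pathway chosen after its values were seen, was at -0.10 (adjusted p = 0.559).

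Antigen presentation and inflammatory lists were not called by camera either, while fry called MHC class I genes higher and immediate early genes lower (adjusted p = 0.00482 each). Of 17 MHC class I genes, 4 rose, 0 fell and 13 did not pass, also adjusted over the list alone (median 0.070, adjusted p = 0.411), and B2M rose by 0.27 and ERAP1 by 0.25. Both calls were lost with the deposited values taken as already normalised (0.062 and 0.034, adjusted p = 0.202 and 0.566) and with limma without the trend (adjusted p = 0.0616 and 0.0695). Of 6 MHC class II genes, 0 rose, 2 fell and 4 did not pass, also adjusted over the list alone (median -0.28, unchanged with IFI30 at its bound; adjusted p = 0.140). IFI30, a lysosomal thiol reductase gene, had 77 and 80 counts in control and 0 in both overexpression libraries, at least 22.1-fold lower against 3 counts per library, and 44.6% of its words occur in another gene. CTSS fell by 0.37. Of 22 NF-kappaB targets, 5 rose, 3 fell and 14 did not pass, also adjusted over the list alone (median 0.064, mean -0.012, adjusted p = 0.787). NFKB1 (0.39) and RELB (0.95) rose, and ICAM1 (-2.10) and BCL2A1 (-3.05) fell. Of 17 immediate early genes, 1 rose, 3 fell and 13 did not pass (0 and 3 adjusted over the list alone; median -0.14, adjusted p = 0.274), with FOS at -0.83 and ZFP36 at -0.49. Of 14 MAPK feedback genes, 2 rose, 4 fell and 8 did not pass, also adjusted over the list alone (median 0.086, mean -0.17, test lower, adjusted p = 0.787). DUSP6 fell by 0.33.

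In the main test the remaining lists were called neither by camera nor by fry. Of 53 G2/M genes, 9 rose, 5 fell and 39 did not pass, also adjusted over the list alone (median 0.006, adjusted p = 0.787), with MKI67 at 0.31 and CENPF at 0.28. Of 37 p53 targets, 3 rose, 7 fell and 27 did not pass, also adjusted over the list alone (median -0.004, mean 0.011, test lower, adjusted p = 0.851), with CYFIP2 at 0.37 and MDM2 at -0.24. Of 16 BCL2 family genes, 2 rose, 3 fell and 11 did not pass (3 and 4 adjusted over the list alone; median 0.013, mean -0.15, test lower, adjusted p = 0.851). BCL2 itself rose from 320 ± 0.775 to 412 ± 12.9 CPM (log2 fold change 0.36). Of 71 nuclear-encoded oxidative phosphorylation genes, 6 rose, 9 fell and 56 did not pass (6 and 8 adjusted over the list alone; median 0.017, test lower, adjusted p = 0.799), with ATP5F1C at -0.33 and SDHC at -0.29. Of 28 cholesterol synthesis genes, 6 rose, 3 fell and 19 did not pass (6 and 4 adjusted over the list alone; median 0.039, adjusted p = 0.851), with SCD at -0.25 and INSIG1 at -0.29. Of 37 ATF4 and unfolded protein response genes, 8 rose, 6 fell and 23 did not pass (10 and 6 adjusted over the list alone; median 0.046, adjusted p = 0.787), with SLC7A11 at 0.51 and HSP90B1 at -0.19. Of 41 replication-dependent histone genes, 7 rose, 9 fell and 25 did not pass (7 and 10 adjusted over the list alone; median -0.046, adjusted p = 0.274), with H2AC8 at -1.31 and H1-2 at -0.28; with the deposited values taken as already normalised it was called lower (adjusted p = 0.00369), as it was without the overexpression library of lane 6 (adjusted p = 0.0385). Of 19 senescence-associated secretory genes, 2 rose, 5 fell and 12 did not pass, also adjusted over the list alone (median -0.050, adjusted p = 0.475), with MMP9 at -2.80 and IGFBP4 at -0.74.

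Markers of other blood lineages and of stroma were few. Of 9 measured megakaryocyte and platelet genes, 2 rose, 1 fell and 6 did not pass, also adjusted over the list alone (median 0.11, adjusted p = 0.799). The most abundant, NRGN and CLEC1B, were at 0.11 (adjusted p = 0.239) and -0.06 (adjusted p = 0.708). Of 6 lymphoid genes, 1 rose, 0 fell and 5 did not pass, also adjusted over the list alone (median 0.15, adjusted p = 0.816). PAX5 rose by 0.53, a call lost with DESeq2 (adjusted p = 0.0611), and NCAM1 was at -0.02 (adjusted p = 0.733) with 278 CPM in control. Of 4 erythroid genes, 2 rose and 2 did not pass, also adjusted over the list alone; CA2 rose by 0.58 and the transferrin receptor gene TFRC by 0.44. Of 4 fibroblast and epithelial genes, 1 fell and 3 did not pass, also adjusted over the list alone. TAGLN fell by 0.52, a call lost without the control library of lane 6 (-0.43, adjusted p = 0.0828) and with DESeq2 (adjusted p = 0.109), and PDGFRB was at 0.12 (adjusted p = 0.555). The erythroid and the fibroblast and epithelial lists were too short for a list test, and 0 genes of the nuclear and small non-coding RNA list were tested.

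Further genes named above lost their call under 1 or both of 2 settings. With limma without the trend these were PARP14, IFIH1, CTSS, MYC, STAT6, ZFP36, CDK6, PAX5, TAGLN, MCM2, MKI67, CENPF, MDM2, RPS20, RPL17, RPL37, SDHC, MT-ND2, SCD, INSIG1, HSP90B1, HSPA8 and H1-2 (adjusted p between 0.0502 and 0.0873). With the deposited values taken as already normalised these were PARP14, MYC, MCM6, CENPF, RPS20, RPL17, MT-ND2 and HSPA8 (adjusted p between 0.0545 and 0.857).

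Other genes named above with at least 10% of their words in another gene were UHRF1 (27.0%), RPL17 (26.2%), HSPA8 (21.4%), RPS27 (20.8%), TYMP (18.6%), ATP5F1C (16.9%), RPS20 (16.2%), HK2 (15.5%), HSP90B1 (15.2%), RNASE2 (15.2%), APOL1 (13.9%), MDM2 (13.2%), SCD (12.6%), SKA1 (10.6%) and FSCN1 (10.4%).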

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

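The lane term, the values taken as already normalised and the GC and length correction were chosen after seeing the data. No paired analysis was possible by replicate number, because the columns carry none. Paired by lane, as a term of the model, 4635 genes were called (2282 higher, 2353 lower) and 10 lists, without the granulocyte list; deviations of libraries of the same lane correlated at 0.042 across genes, and of the principal components after the first, the second (21.4%) separated the lanes and the third (19.6%) set the control library of lane 1 and the overexpression library of lane 6 apart from the other 2. Of 3512 genes called (1739 higher, 1773 lower), 361 (145 and 216) also changed by 2-fold or more. DESeq2 called 1987 (969 and 1018), limma without the trend 1154 (554 and 600, with 96 of 340 list members) and edgeR with no filter on low counts 2404 (1118 and 1286, with 16818 genes tested). In the simulation, limma without the trend recovered 0% of genes changed 1.2-fold or 1.5-fold, 32% at 2-fold and 70% at 4-fold. This was below edgeR at each size, so its lower count went with lower power. Why DESeq2 and the unfiltered test called fewer genes was not tested. Leaving out 1 library gave 2311 to 2973 genes, 1125 to 1465 higher and 1186 to 1508 lower, with fewer samples and the lone library assumed to vary like the other group. Values taken as already normalised gave 5965 (530 and 5435), since every fold then carries the difference in library totals, and 7 lists, 5 of the 11 besides STAT3 targets and replication-dependent histones. No list was called with an estimated correlation (0 of 31, lowest adjusted p 0.250). The estimate was below the preset 0.01 for the glycolysis and hypoxia (-0.0077), G1/S (-0.020), heat shock (-0.054), adhesion (-0.0037), granulocyte (-0.032) and stem (-0.031) lists. It was above for the ribosomal protein (0.265), mitochondrially encoded (0.1785), cytokine receptor (0.105), monocyte (0.030) and MYC (0.016) lists. For the former, the loss came with few degrees of freedom and not with higher correlation. The cytokine receptor, monocyte and macrophage, G1/S, glycolysis and hypoxia, and adhesion and homing lists were called under all 14 other settings that gave different list p-values, the stem and progenitor list under 9, the granulocyte list under 4, and the mitochondrially encoded list under 7 of 13; 4 further settings repeated others (both prior counts repeat the main p-values, the 2 median-of-ratios factors agree, and so do list tests of the 2 limma fits). SOCS1 ranged from 0.44 to 1.91 when 1 library was left out, and passed the threshold only without the control library of lane 1 (1.91, adjusted p = 0.0291) and with the lane term (1.08, adjusted p = 0.0399), over a range of adjusted p up to 0.487; the cause was not tested. The lowest within-group correlation, 0.987, was 0.990 with no filter and 0.989 with a mean count of at least 50, which change the genes compared. Across 148 named genes and 19 settings, 2649 values kept their direction and side of the threshold, 122 no longer passed, 7 newly passed and 13 changed sign. With values taken as already normalised, the log2 fold changes of CALR (-0.12), CD74 (-0.15), EPOR (-0.057), NRGN (-0.10), PDGFRB (-0.089), ACTA2 (-0.12) and HSP90AA1 (-0.032) changed sign, by the same shift in scale. CALR was at -0.0086 under quantile normalization, where the cause was not tested. Leaving out 1 library changed the sign of 5 genes that had not passed, with fewer samples: EPOR (-0.041 to 0.33), BLNK (-0.087 to 0.89), ACTA2 (-0.0015 to 0.18), NCAM1 (-0.038 to 0.00028) and CLEC1B (-0.16 to 0.034). Groups of 2 limit what can be tested; SOCS1 had 12 to 45 counts.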

Other observations

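Symbol families were grouped after the data were seen, by the letters before the first digit of the symbol, for the 218 families with at least 8 tested members. Of 9 tested integrin beta symbols (root ITGB, which includes some binding partners), 5 fell and 0 rose by edgeR (camera with a preset correlation, adjusted p = 9.5e-05), among them ITGB1 at -0.35 and ITGB5 at -2.52. Of 10 SIGLEC genes, sialic acid-binding receptors of myeloid cells, 4 fell and 0 rose (adjusted p = 0.0417), with SIGLEC6 falling from 55.2 to 28.1 CPM and SIGLEC14 from 49.0 to 31.7 CPM. Of 10 MCM symbols, 8 rose and 0 fell (adjusted p = 2.73e-04), including MCM10 at 0.48 and MCM4 at 0.20. The other 3 of the 6 families that passed were CD (7 of 50 rose, 24 fell, adjusted p = 1.75e-04), RPL (34 of 89 rose, 4 fell, adjusted p = 1.86e-04) and RPS (21 of 59 rose, 9 fell, adjusted p = 0.0417). The ITGB, MCM, RPL and RPS families share members with lists called above, such as ITGB2, MCM5, RPL17 and RPS27. They are therefore no separate support for those lists. With an estimated correlation, where 4 libraries leave few degrees of freedom, each of the 6 families that passed had adjusted p = 0.991 by camera. Genes with at most 3 counts in both libraries of a group and at least 30 in both of the other numbered 3 for control (FAM220A, IFI30 and ULK4P2) and 3 for overexpression (CPEB2, CT45A7 and SAGSIN1), against 4 for the split by lane. Chromosome medians lay between -0.025 and 0.057, and medians over 41 neighbouring genes between -0.19 and 0.36.

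The tests of a 10-fold rise, of exchanged labels, of a lower share of monocytic cells and of shared words in the glycolysis and hypoxia list below were chosen after the results were seen, the last with its value already known. SOCS1 did not pass the threshold in the libraries labelled overexpression. Low depth as the reason for missing a 10-fold rise is argued against by the upper 95% bound of the fold, 4.101. Loss of reads to genes with the same sequence is argued against by the 0% of SOCS1 31-base words found in another gene. SOCS1 was higher in both lanes (0.61 and 1.53) and passed with lane as a term of the model (1.08, adjusted p = 0.0399), the direction the labels give. Exchanged labels still cannot be told apart from correct ones, because the lower bound of the fold without that term, 0.9786, lies below 1 with 2 libraries per group, and the value was 0.44 (adjusted p = 0.487) without the control library of lane 6. An open reading frame whose sequence the annotation does not count under SOCS1 stays open and untested.

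The monocyte and macrophage list was lower. A trend on GC content or transcript length as the whole cause is argued against by its adjusted p of 5.744e-08 after that trend was removed, with the median at -0.335 against -0.338. Reads shared between near-identical genes are not excluded. The members with the fewest shared words had a median of -0.4008 (SE 0.249), below 0 by more than its SE, the mark set beforehand. That mark is lenient, and the SE treats the members as independent, so the median is not clearly apart from 0. A lower share of 1 monocytic population as the whole cause stays open. The test asked whether any member rose, and the 3 that did, MS4A6A among them, were known before it was chosen. Rises were also common among all genes (1739 of 12342), so this test cannot decide. SOCS1 overexpression and the vector type, which differ between the groups together, both stay open and untested. The call does not hold with an estimated correlation, where 4 libraries leave few degrees of freedom.

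The ribosomal protein list was higher. It stayed so after the GC and length trend was removed (adjusted p = 1.278e-12), which argues against that trend as the whole cause. Its members with the fewest shared words had a median of 0.1792 (SE 0.030), past the mark set beforehand, and the other members 0.108. The rise was thus not confined to members with more shared words. Shared reads are not excluded, since the former still shared up to 12.68% of their words. The SE also treats members as independent (estimated correlation 0.265). The call was lost by camera with an estimated correlation (adjusted p = 0.489) and by fry (adjusted p = 0.0503). It was also lost by camera with the deposited values taken as already normalised (adjusted p = 0.919), where the median of all genes was -0.21. The lowest median of the list under any setting in which lists were tested was -0.064. SOCS1 overexpression and the vector type both stay open and untested. The glycolysis and hypoxia list kept its lower call after the same correction (adjusted p = 3.062e-17), but not by camera with an estimated correlation (adjusted p = 0.250). That estimate, -0.0077, was below the preset 0.01, so a higher correlation did not cost the call. The members of this list with the fewest shared words had a median of -0.1734 (SE 0.185), which does not exclude shared reads. The 3 ways to split 4 libraries into pairs are too few for a share under 0.05. The real split gave 3512 genes and the highest other split 1. In the other splits the difference between control and overexpression lies within the groups and widens their spread. Few calls were therefore bound to follow there, and the comparison cannot back the 3512 calls.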
